A study of Mus musculus with 12 samples.

How the data were processed

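RNA was sequenced from 12 cultures of mouse embryonic fibroblasts, 3 biological replicates in each of 4 groups, treated with WM-2474 at 10 µM or with DMSO for 96 h or 240 h. Per the labels, the libraries were made with a stranded mRNA kit and unique indexes. The authors deposited a table of raw counts per gene, whole numbers without normalization, with the exon length of each gene in base pairs. Per the submitters' processing notes the counts came from featureCounts on mm10. The aligner, the tool versions, the annotation and the strand and multiple-mapping settings of the counting were not given in the sources used here, so that antisense genes and genes with near-identical copies are uncertain. Each count column was matched to its sample by treatment, time and replicate number, and 0 columns stayed unmatched.

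Of 27179 table entries, 874 had no gene identifier and were left out; they held 0.547 to 0.648% of a library's counts. The 26305 identifiers were named with the GRCm38.p6 annotation, which gave a symbol to 25275 of them (96.1%). Library totals were 7313007 to 26019167 counts, and 16036 to 17307 genes were detected. A floor of 3 counts per library and 95% intervals express precision, for counting error and for the fitted spread respectively. Pairs of replicates were checked for duplication, and a chi-square per degree of freedom of 2.02 to 4.99 showed no identical pair.

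The comparisons, tests, gene lists, rule for naming genes and the alternative settings to be tried were fixed before the data were examined. The contrasts were WM-2474 against DMSO at 96 h and at 240 h, the average of both, the difference between both, and 240 h against 96 h within each treatment. Genes were filtered with filterByExpr by group, which kept 13499, and counts were scaled with TMM factors (1.04 to 1.05 at 96 h, 0.943 to 0.967 at 240 h). edgeR 4.0.16 fitted all 12 libraries with 1 coefficient per group (robust dispersion, common biological variation of 5.22%), and its quasi-likelihood F test gave two-sided p-values that were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Values given as ± beside a log2 fold change are standard errors, and those beside CPM are standard deviations of 3 libraries. The smallest p that an exact permutation of 3 against 3 libraries allows is 0.1, so that the calls rest on the pooled model. Analyses ran in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

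Gene lists numbered 32 and could share members, such as Cdc6 and E2f2 in the KAT6A-linked and the DNA replication lists. They covered CDK inhibitors, proliferation genes linked to KAT6A, acetyltransferases with KAT6 complex subunits, Hox genes, DNA replication and G1/S, mitosis, senescence-associated secretion, p53 targets, aryl hydrocarbon receptor targets, NRF2 targets, other enzymes and pumps for foreign compounds, integrated stress response, unfolded protein response, heat shock, cholesterol synthesis, lysosome, hypoxia, interferon response, immediate early genes, fibroblast matrix and myofibroblast genes. Others held markers of adipocytes, bone and cartilage, macrophages and blood cells, endothelium, epithelium, neural cells, muscle and red cells, and ribosomal proteins, mitochondrially encoded genes and sex-linked genes. These others served as checks of RNA quality, other cells and labels. A list needed 3 tested members, which left 31, since no red cell marker passed the filter. Camera of limma tested each list on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists within a contrast. The same test with an estimated correlation kept 0 calls in each of the 6 contrasts. Members were also adjusted over the list alone. Another 6 marker lists (B lineage, T lineage, myeloid, red cell, pan-leukocyte, and the 8 genes in which the signal was first seen) were written after the counts had been viewed.

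Genes are named by a rule. It takes Cdkn2a, Cdkn2b, Cdkn1a, Cdc6, E2f2, Melk, Ezh2, Kat6a, Kat6b and Kat7 in treatment comparisons; the 10 largest rises and falls among passing genes with at least 1 CPM in a group and libraries that do not overlap (5 and 5 for the difference), or the smallest p up to 3 per direction where fewer pass; and per list the 2 rising and 2 falling members with the smallest p, or the single smallest where none passes. Of the largest time changes, those without an informative name or close to the floor are left out of the text. Names outside this rule were chosen after their values were seen, which holds for members that passed only over their list (Runx2, Abcg2, Abcb1a), for the genes of other settings (Dnm3os), for Cox8a and for B-lineage genes.

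Alternatives were RLE size factors, library totals, no filter, a filter of over 1 CPM in at least 3 libraries, DESeq2, limma-voom with quality weights, the replicate number as a block, a test against a fold of 1.2, fits of only the libraries compared, each library left out in turn, fry and an estimated correlation for lists, and overlap at an unadjusted p of 0.01. Pairing by replicate number was checked by correlating residuals and was taken to hold where all 3 correlations exceeded 0.1. That was so at 96 h but not at 240 h, where the correlations were weaker yet above those of different numbers. Power was tested on simulated data of the same design, in which 49 or 50 genes were changed at each fold and the cholesterol synthesis list was raised by 1.2-fold. Libraries were drawn independently from the fitted spread, without the pairing found at 96 h. At folds of 1.2, 1.5, 2 and 3 the test recovered 32.7, 89.8, 91.8 and 98.0% at 96 h, 28.6, 77.6, 85.7 and 98.0% at 240 h, and 53.1, 95.9, 93.9 and 100% in the average. For the difference it recovered 10, 60, 89.8 and 93.9%. Of the simulated calls 5.85 to 6.56% were false, and 94.9 to 95.3% of intervals held the true value.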

Results

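Gene expression was measured by RNA sequencing in cultured mouse embryonic fibroblasts from male C57BL/6 embryos. These primary cells have a limited lifespan in culture and are a common model of cell cycle arrest and senescence. The cultures received WM-2474 at 10 µM, which the labels call an inactive control compound, or the solvent DMSO, and RNA was taken after 96 h or 240 h. Related compounds of the same naming series inhibit the lysine acetyltransferases KAT6A and KAT6B, and no active compound was among these samples. There were 4 groups of 3 biological replicates, 12 libraries in all. Counts assigned to genes at 96 h were 16148590, 10961741 and 12917864 in DMSO replicates 1, 2 and 3, and 14279614, 11483842 and 11222253 in WM-2474 replicates 1, 2 and 3. At 240 h they were 7313007, 7701112 and 26019167 in DMSO replicates 1, 2 and 3, and 9585953, 13803413 and 9172540 in WM-2474 replicates 1, 2 and 3. A floor of 3 counts corresponded to between 0.115 and 0.410 CPM per library, where CPM are counts scaled to a common library size. The floor covers counting error only, whereas the 95% intervals come from the fitted spread between replicates. The labels mention no molecular identifiers. The 10 most abundant genes took 6.14 to 8.68% of a library's counts, and the mitochondrially encoded genes took 1.28 to 1.57%. Positions refer to GRCm38, the build that mm10 represents.

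Culture time was the main difference between libraries. The first principal component of log2 CPM held 53.8% of the variance, with the 96 h libraries between -24.2 and -21.6 and the 240 h libraries between 18.0 and 27.3. The next component held 7.75%, with WM-2474 240 h replicate 1 at -18.5, DMSO 240 h replicate 2 at 20.9 and the other 10 libraries between -6.14 and 6.15. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were expressed in all 12 libraries, with Ddx3y between 62.1 and 78.2 CPM. Xist, the transcript that silences an X chromosome in female cells, had 5.06 and 4.29 CPM in DMSO 240 h replicates 1 and 2 and at most 0.929 CPM in the other 10 libraries. The same pair of libraries held transcripts of the B-cell lineage, whose 26 markers summed to 22.8 and 26.7 CPM there, 2.96 CPM in DMSO 240 h replicate 3 and 2.30 to 6.11 CPM with WM-2474 at 240 h. At 96 h they summed to 4.49 to 6.84 CPM with DMSO and 2.44 to 3.39 CPM with WM-2474, and Xist had 0.542 to 0.929 and 0 to 0.210 CPM.

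**Figure D1:**
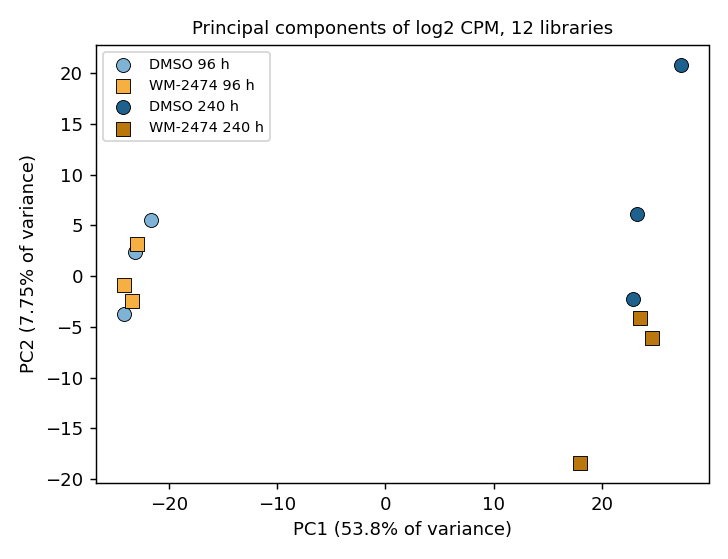
Principal components of log2 CPM in 12 libraries, with the first component (53.8% of the variance) on the x axis and the next (7.75%) on the y axis, and a point per library coloured by treatment and time. All 96 h libraries lie at or below -21.6 and all 240 h libraries at or above 18.0 on the first component.

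The comparison of WM-2474 with DMSO at 96 h asked what the control compound itself did to transcript levels after the shorter exposure. None of 13499 tested genes passed an adjusted p of 0.05 in edgeR (n = 3 per group). The Cdkn2a locus, which encodes the senescence-linked proteins p16INK4a and p19ARF, had 109 ± 16.5 CPM (SD) with DMSO and 103 ± 10.3 with WM-2474, a log2 fold change of -0.07 ± 0.10 (SE). The p53 target and cell cycle inhibitor Cdkn1a stood at 385 ± 11.5 and 385 ± 15.8 CPM, and the replication licensing factor Cdc6 at 14.2 ± 2.16 and 12.9 ± 0.112 CPM. The acetyltransferase genes Kat6a, Kat6b and Kat7 had log2 fold changes of 0.10, -0.09 and -0.02, with intervals of -0.03 to 0.23, -0.25 to 0.06 and -0.13 to 0.08. The genes with the smallest p did not pass. They were the growth factor response genes Egr1 (0.31 ± 0.07) and Btg2 (0.19 ± 0.05) and the myosin light chain kinase Mylk (0.28 ± 0.08) with higher values, and the leukocyte receptor gene Il2rg (-1.25 ± 0.38), Acat3 (-0.28 ± 0.08) and the ribosome assembly factor Pno1 (-0.23 ± 0.07) with lower ones. B-lineage markers and Xist were also lower in all 3 WM-2474 libraries, which chance gives in 10% of groupings for either direction. An unadjusted p under 0.05 was reached by 283 genes, against 675 expected by chance, and DESeq2 and limma-voom also called 0 genes, with 109 and 399 under that unadjusted level. The 2 groups' libraries did not overlap for 7.45% of genes, where chance gives 10%. The replicate numbers paired the samples at this time (correlations of 0.301, 0.235 and 0.191 between libraries of the same number). With the replicate number as a block and only the 96 h libraries, 3 genes were higher, namely Dnm3os, Egr1 and Tmsb10, and 846 of 13377 genes (6.32%) reached an unadjusted p under 0.05, more than the 5% that chance gives. With all 12 libraries and the block the counts were 0 and 310. That block fits 1 replicate effect to both times, whereas correlations of equal numbers across times were -0.00783 to 0.132. It therefore cannot stand in for the pairing at 96 h. The main fit had no block, so that the pairing added to its spread. Its low counts at 96 h may thus understate an effect.

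Of 31 gene lists tested at 96 h, limma's camera called 4 with a preset correlation. Immediate early genes were higher as a list (17 tested, median log2 0.06, adjusted p = 0.0394; adjusted p = 0.686 with an estimated correlation), and Egr1 was the only member to pass when adjusted over the list alone. The 13 mitochondrially encoded genes, which encode respiratory chain proteins, were also higher (median 0.08, adjusted p = 0.000811; 0.686 as the adjusted p with an estimated correlation). The genes of cholesterol synthesis (24 tested, median -0.07, adjusted p = 0.000811) and of the integrated stress response (22 tested, median -0.06, adjusted p = 0.00127) were lower. Their adjusted p with an estimated correlation was 0.817 and 0.686, and no member of either passed, including the sterol reductase Tm7sf2 (-0.16 ± 0.08) and the alanine aminotransferase Gpt2 (-0.14 ± 0.06). Adjusted over the list alone, the p53 target Btg2 and the bone transcription factor Runx2 (0.22 ± 0.06) also passed within their lists, which were not called. The acetyltransferases and subunits of the KAT6 complex (11 tested, adjusted p = 0.657) and the targets of the aryl hydrocarbon receptor, a sensor of foreign compounds (6 tested, adjusted p = 0.141), had 0 members past the test. Single libraries decided these list calls. The lists called higher numbered 1 without WM-2474 96 h replicate 1, 2 or 3 and 0 without DMSO 96 h replicate 1 or 2, and those called lower numbered 1 without WM-2474 96 h replicate 1 or DMSO 96 h replicate 2 or 3.

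At 240 h the same question was put to the longer exposure, and 4 genes were higher with WM-2474, each by less than 1.5-fold, while none was lower. Ptma, which encodes the acidic nuclear protein prothymosin alpha, rose from 118 ± 2.91 to 149 ± 4.95 CPM (log2 0.33 ± 0.06, interval 0.21 to 0.44, adjusted p = 0.017; SD, n = 3). Tmsb10, which encodes the actin monomer binding protein thymosin beta 10, rose from 167 ± 6.4 to 212 ± 16.4 CPM (0.34 ± 0.06, interval 0.22 to 0.46, adjusted p = 0.0231). Sorcs2, which encodes a neurotrophin and sorting receptor, rose from 130 ± 3.61 to 161 ± 6.09 CPM (0.30 ± 0.05, interval 0.20 to 0.41, adjusted p = 0.017). Counts assigned to Gm8623, annotated as a pseudogene, rose from 17.4 ± 1.21 to 25.8 ± 1.24 CPM (0.57 ± 0.10, interval 0.37 to 0.77, adjusted p = 0.017), but its sequence shares 301 of 406 words of 31 bases with the ribosomal protein gene Rps16, so that the gene behind these reads is uncertain. For each of the 4 genes all 3 WM-2474 libraries lay above all 3 DMSO libraries. In the annotation, Ptma (gene 19231) spans chromosome 1 from 86526557 to 86530712, Tmsb10 (19240) chromosome 6 from 72957347 to 72958748, Sorcs2 (81840) chromosome 5 from 36017180 to 36398197, and Gm8623 (667422) chromosome 8 from 47632276 to 47632779. The count of genes lower was 0 in edgeR, in DESeq2 and in limma-voom, with 1099, 697 and 1156 genes of either direction at an unadjusted p under 0.05. By chance 675 would be expected, and the edgeR count held 644 genes higher and 455 lower. DESeq2 called 11 genes higher, 3 of them among the 4, but its independent filtering left 10207 of 13499 genes, Gm8623 included, without an adjusted p. Limma-voom called 7 higher, with all 4 among them. Without a filter 39 genes were higher and 8 lower. The replicate block gave 7 higher, and a fit of only the 240 h libraries gave 15. In fits of these libraries chosen after the data were seen, 79 were higher and 12 lower with the block, and 20 were higher by limma-voom.

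Some settings ended the 4 calls at 240 h, although over all alternatives the log2 fold change stayed within 0.29 to 0.35 for Ptma, 0.28 to 0.38 for Tmsb10, 0.27 to 0.33 for Sorcs2 and 0.53 to 0.60 for Gm8623. No gene was called without WM-2474 replicate 1, WM-2474 replicate 2, DMSO replicate 1 or DMSO replicate 2 at 240 h. Without DMSO 240 h replicate 3, 7 genes were higher and 12 lower, and without WM-2474 240 h replicate 3 the count was 5. The former fit left only DMSO 240 h replicates 1 and 2 as the DMSO group. An effect of the compound on its lower genes cannot be told apart from the B-lineage and Xist signal of these libraries. No other single library left out gave a lower gene at 240 h. DMSO 240 h replicates 1 and 2, which held the B-lineage markers and Xist, also had the fewest counts, and without both the 4 genes had a median log2 fold change of 0.31 with 0 calls (adjusted p = 0.994 for each). Over all alternative settings the adjusted p of these genes ranged from 3.04e-06 to 1. None of the 4 passed a test against a fold of 1.2.

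**Figure D2:**
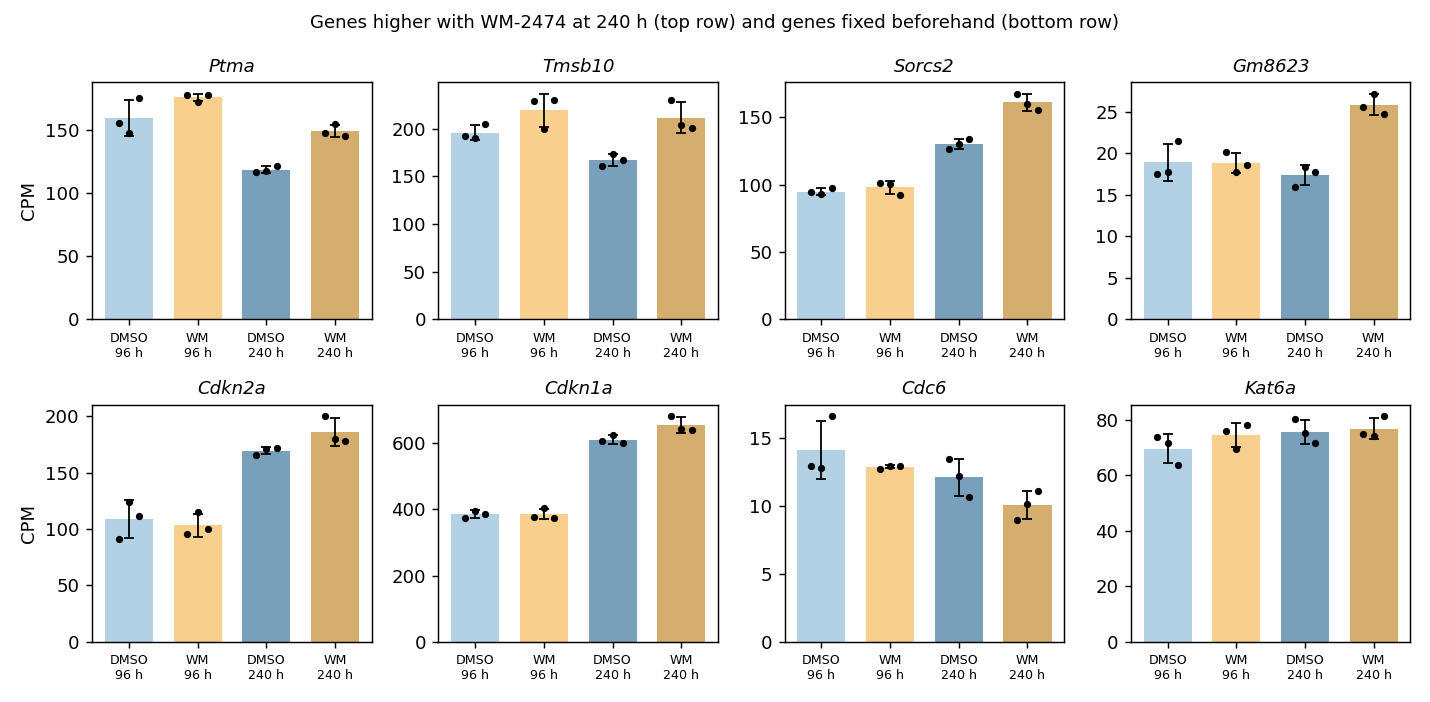
Expression in CPM (y axis, from 0) in the 4 groups (x axis), with bars at the mean of 3 libraries, error bars of 1 SD and a point per library. The top panels show Ptma, Tmsb10, Sorcs2 and Gm8623, whose WM-2474 libraries at 240 h all lie above the DMSO libraries, and the bottom panels show Cdkn2a, Cdkn1a, Cdc6 and Kat6a, which did not pass the treatment test at either time.

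Genes of senescence, proliferation and histone acetylation did not pass at 240 h. Cdkn2a had 170 ± 3.4 CPM with DMSO and 186 ± 12.2 with WM-2474 (log2 0.13, interval -0.08 to 0.35). Cdkn1a had 610 ± 13.1 and 655 ± 23.2 CPM (0.10, interval 0.01 to 0.19, adjusted p = 0.571), and the INK4 inhibitor Cdkn2b had a log2 fold change of 0.03 (interval -0.10 to 0.17). Cdc6 (-0.22, interval -0.49 to 0.05), the cell cycle transcription factor E2f2 (-0.30, interval -0.80 to 0.19), the mitotic kinase Melk (-0.12, interval -0.30 to 0.07) and the histone methyltransferase Ezh2 (0.01, interval -0.15 to 0.16) have been linked to KAT6A. As a list these 4 genes had a median of -0.17 (adjusted p = 0.0812). Kat6a (0.03), Kat6b (-0.14) and Kat7 (-0.12, interval -0.23 to 0.00, adjusted p = 0.601) did not pass either. The smallest p among lower genes belonged to the mitochondrial carrier Ucp2 (-0.64 ± 0.15, adjusted p = 0.334), the histone chaperone Nasp (-0.28 ± 0.07) and Rpl6l (-0.23 ± 0.06), of which the last resembles the ribosomal protein gene Rpl6.

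Among the 31 lists at 240 h, camera called cytosolic ribosomal proteins higher (38 tested, median 0.11, adjusted p = 3.99e-07; adjusted p = 0.629 with an estimated correlation). Adjusted over the list alone, 9 members rose, although over all genes even Rpl18 (0.32 ± 0.07, adjusted p = 0.334) did not pass. Mitochondrially encoded genes were higher as well (13 tested, median 0.11, adjusted p = 9.89e-05, and adjusted p = 0.646 with an estimated correlation). They took 1.28, 1.29 and 1.43% of counts in DMSO replicates 1, 2 and 3. With WM-2474 they took 1.41, 1.39 and 1.33% in the same order. The rise therefore rested on DMSO replicates 1 and 2, while DMSO replicate 3 lay above every WM-2474 library. In that list 5 members rose when adjusted over the list alone, and the smallest p was that of the ATP synthase subunit ATP6 (0.19 ± 0.05). CDK inhibitors (7 tested, median 0.10) and fibroblast matrix genes (21 tested, median 0.08) were called higher, each with an adjusted p = 0.043, which became 0.646 and 0.855 as adjusted p with an estimated correlation. No member of either passed, and the elastin cross-linking enzyme Loxl1 (0.19 ± 0.06) had the smallest p among matrix genes. DNA replication and G1/S genes (37 tested, median -0.08) and mitosis genes (30 tested, median -0.11) were lower, each with an adjusted p = 6.93e-06, and with an adjusted p = 0.629 and 0.646 with an estimated correlation. None of their members passed, with Rrm1, a subunit of ribonucleotide reductase, at -0.17 ± 0.05 and the topoisomerase Top2a at -0.17 ± 0.05. Among other enzymes and pumps for foreign compounds (9 tested, list not called), Gstp1 rose (0.21) and the efflux pumps Abcb1b (-0.29), Abcg2 (-0.20) and Abcb1a (-1.1) fell when adjusted over the list alone, and the myeloid marker Lyz2 (1.24 ± 0.46) rose within its list on the same terms, from 3 and 2 counts in DMSO replicates 1 and 2, at or under the floor. The acetyltransferase list (adjusted p = 0.689) and the aryl hydrocarbon receptor targets (adjusted p = 0.972) again had 0 members past the test. The lists called higher numbered 2 without WM-2474 240 h replicate 1 or 3, without DMSO 240 h replicate 1, 2 or 3, and without DMSO 240 h replicates 1 and 2 together.

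Averaged over both times, with 6 libraries per treatment, Ptma (log2 0.23 ± 0.04) and Tmsb10 (0.25 ± 0.04) were higher with WM-2474, each at an adjusted p = 0.0172, and 0 genes were lower. DESeq2 and limma-voom also called 2 genes higher and 0 lower, and 763, 466 and 779 genes reached an unadjusted p under 0.05 in edgeR, DESeq2 and limma-voom. Sorcs2 (0.18 ± 0.04, adjusted p = 0.215), the sugar transporter Slc2a6 (-0.39 ± 0.10) and the splicing factor Smu1 (-0.14 ± 0.04) did not pass. Ribosomal protein genes (median 0.05, adjusted p = 4.2e-05) and mitochondrially encoded genes (median 0.10, adjusted p = 4.96e-07) were called higher, with 7 and 6 members up when adjusted over the list alone. The 240 h part of the mitochondrial rise rested on DMSO 240 h replicates 1 and 2. The list linked to KAT6A (median -0.14, adjusted p = 0.0173), DNA replication genes (median -0.04, adjusted p = 0.00114) and mitosis genes (median -0.05, adjusted p = 6.5e-05) were called lower, with 0 members past the test. With an estimated correlation the adjusted p was 0.68 for the ribosomal, mitochondrial and KAT6A-linked lists and 0.78 for DNA replication and mitosis. The KAT6A-linked and DNA replication lists share Cdc6 and E2f2, so that their calls are not separate. No gene was called in the average without WM-2474 96 h replicate 1 or 3, WM-2474 240 h replicate 2, DMSO 96 h replicate 1 or 2, DMSO 240 h replicate 1 or 2, the last 2 together, or with library totals in place of TMM factors. Over all alternatives the log2 fold change nevertheless stayed within 0.21 to 0.27 for Ptma and 0.22 to 0.28 for Tmsb10. Without DMSO 96 h replicate 3 the count was 4, and without DMSO 240 h replicate 3 it was 3 higher and 10 lower. The latter fit left only the libraries with B-lineage markers and Xist as DMSO at 240 h. Lists called lower numbered 0 without WM-2474 240 h replicate 1 and 5 without WM-2474 240 h replicate 3, DMSO 96 h replicate 1 or DMSO 240 h replicate 2, and lists called higher numbered 4 without WM-2474 96 h replicate 1.

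**Figure D3:**
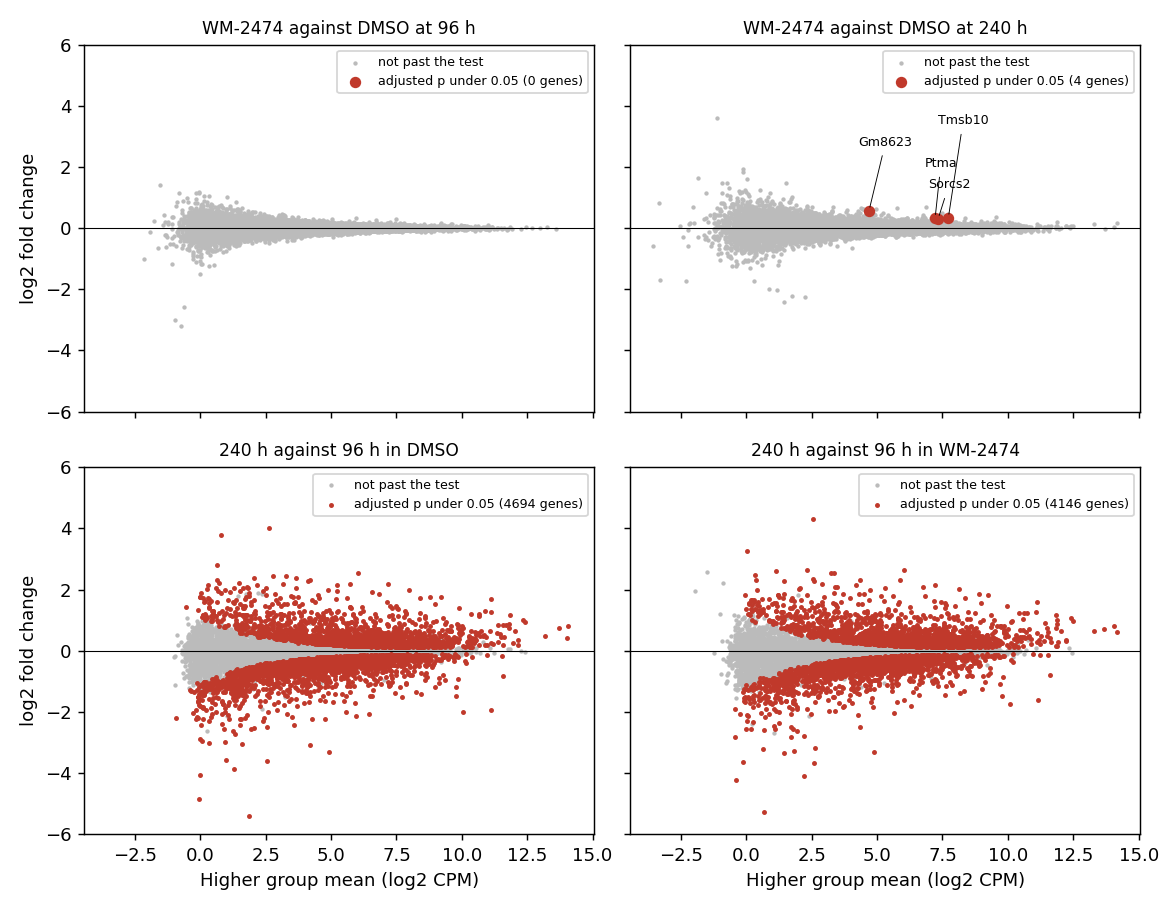
Log2 fold change (y axis) against the higher of the group means in log2 CPM (x axis) for each tested gene, in panels for WM-2474 against DMSO at 96 h and 240 h and for 240 h against 96 h in each treatment. Red points passed an adjusted p of 0.05, which were 0 and 4 genes in the treatment panels and 4694 and 4146 genes in the time panels.

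The difference between the effects of WM-2474 at 240 h and at 96 h was tested as an interaction. No gene passed in edgeR (smallest adjusted p = 0.977), DESeq2 or limma-voom, with 625, 297 and 806 genes at an unadjusted p under 0.05. Cdkn2a differed by 0.20 (interval -0.11 to 0.51) and Cdkn1a by 0.10 (interval -0.03 to 0.23). Camera called ribosomal proteins (median difference 0.12, adjusted p = 3.67e-05) and the hypoxia response (0.09, adjusted p = 0.0267) higher, with Rpl11 at 0.36 ± 0.12 and the glycolytic enzyme Pgk1 at 0.25 ± 0.08. DNA replication genes (-0.11, adjusted p = 9.68e-05), mitosis genes (-0.11, adjusted p = 0.0017) and targets of the antioxidant factor NRF2 (-0.06, adjusted p = 0.0449) were called lower, with the proliferation marker Mki67 at -0.24 ± 0.09 and the quinone reductase Nqo1 at -0.31 ± 0.14. None of these 5 calls held with an estimated correlation, where the adjusted p was 0.744 for ribosomal, DNA replication and NRF2 genes and 0.788 for mitosis and hypoxia genes. Adjusted over the list alone, the efflux pump Abcb1b (-0.43) differed among enzymes and pumps for foreign compounds and Lyz2 (1.53, with the same counts near the floor) among macrophage markers. Lists called higher numbered 1 without WM-2474 96 h replicate 1, WM-2474 240 h replicate 1 or DMSO 96 h replicate 3, 4 without DMSO 240 h replicate 3, 4 with the replicate number as a block and 5 without WM-2474 96 h replicate 2. Lists called lower numbered 0 without WM-2474 240 h replicate 1. The treatment effects of the separate times shared no libraries, and across 13499 genes they had a Pearson correlation of 0.0605 and a Spearman correlation of 0.0270, where genes are not independent replicates. At an unadjusted p under 0.01, 22 genes were higher at 96 h and 188 at 240 h, with 2 in common (Cox8a and Tmsb10; 0.306 expected, Fisher's exact p = 0.0371, two-sided), and 15 and 77 were lower with 0 in common.

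The size of effect that these data leave open was small for most genes. The median absolute log2 fold change of WM-2474 against DMSO was 0.05 at 96 h and 0.08 at 240 h, with a median SE of 0.09 at each time. The 95% interval of the difference lay within 1.5-fold for 84.2% of genes at 96 h, 80.4% at 240 h and 89.6% in the average, and within 2-fold for 95.2%, 92.2% and 98.3%. At 240 h 14.3% of genes had libraries of both groups that did not overlap, where chance gives 10%. In simulated data of the same design, 89.8% of genes changed by 1.5-fold were recovered at 96 h and 77.6% at 240 h, but only 32.7% and 28.6% of those changed by 1.2-fold. The simulation called 183 genes at 96 h and 171 at 240 h, where the real data gave 0 and 4. Its adjusted threshold was therefore looser, and recovery of isolated changes may be lower.

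Between 96 h and 240 h the transcripts of lipid synthesis and proliferation fell in both treatments. All 24 tested genes of cholesterol synthesis fell with DMSO and with WM-2474 (medians of -1.0 and -0.91), with lanosterol synthase Lss falling from 306 ± 13.2 to 119 ± 3.58 CPM with DMSO (log2 -1.36 ± 0.05, adjusted p = 9.98e-17) and farnesyl diphosphate synthase Fdps from 236 ± 7.25 to 110 ± 6.19 CPM (-1.09 ± 0.05). All 7 adipocyte markers fell too, among them the lipogenic enzymes Scd1 (-1.48 ± 0.05 with DMSO, -1.49 with WM-2474) and Fasn (-0.94 and -0.86). All 30 mitosis genes fell in both treatments (medians -0.43 and -0.54), such as the mitotic kinesin Kif20a, from 115 ± 4.34 to 76.9 ± 0.784 CPM with DMSO (-0.58 ± 0.06, adjusted p = 1.36e-08). Of 37 DNA replication and G1/S genes, 23 fell with DMSO and 31 with WM-2474, and none rose, with thymidine kinase Tk1 at -0.62 ± 0.07 in DMSO and the ribonucleotide reductase subunit Rrm2 at -0.53 ± 0.05 in WM-2474. Adjusted over the list alone, 29 and 33 of these fell. Melk and Ezh2 fell in both treatments, at -0.43 and -0.32 with DMSO and -0.46 and -0.25 with WM-2474, within a list linked to KAT6A of which 2 and 3 of 4 members fell. By camera, the adjusted p of these lists with DMSO and WM-2474 was 1.51e-24 and 8.68e-25 for cholesterol synthesis, 1.17e-05 and 8.82e-07 for adipocyte markers, 9.37e-15 and 3.73e-19 for mitosis, 1.52e-07 and 1.98e-13 for DNA replication, and 0.0476 and 0.013 for the KAT6A-linked list. With an estimated correlation the adjusted p was 0.0851 and 0.0595, 0.0851 and 0.0588, 0.13 and 0.0595, 0.145 and 0.0595, and 0.195 and 0.114 in the same order.

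Genes of the extracellular matrix and of contraction rose over the same interval. Of 21 fibroblast matrix genes, 18 rose with DMSO and 19 with WM-2474 and none fell (median 0.65 in each), with the collagen chain Col6a3 rising from 696 ± 50.6 to 2230 ± 175 CPM with DMSO (1.68 ± 0.05) and by 1.59 with WM-2474. All 15 myofibroblast and contractile genes rose in both treatments (medians 0.88 and 0.91), with smooth muscle actin Acta2 at 0.95 ± 0.05 and the actin nucleator Lmod1 at 1.2 ± 0.05 in DMSO. Camera's adjusted p with DMSO and WM-2474 was 5.83e-13 and 7.37e-16 for matrix genes and 4.05e-15 and 1.55e-15 for contractile genes. With an estimated correlation the adjusted p was 0.0851 and 0.0588 for matrix genes and 0.0851 and 0.0595 for contractile genes.

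Cell cycle inhibitors moved in opposite directions over time. Cdkn1a rose from 385 ± 11.5 to 610 ± 13.1 CPM with DMSO (0.66 ± 0.04, adjusted p = 7.59e-12) and by 0.77 ± 0.04 with WM-2474, and Cdkn2a rose by 0.65 ± 0.10 and 0.85 ± 0.10. Cdkn1b, which encodes p27, fell in both (-0.56 and -0.62), and the list of 7 had 2 members up and 4 down with DMSO and 2 up and 3 down with WM-2474, without a list call. Of 26 p53 targets, 15 rose and 1 fell with DMSO and 16 rose and 2 fell with WM-2474, with the membrane protein Perp at 1.98 ± 0.10 and 1.67 ± 0.10 and the stress protein Sesn1 down at -0.48 and -0.47. Camera called the list of p53 targets higher (adjusted p = 4.12e-06 and 4.34e-07, and 0.0851 and 0.0588 as adjusted p with an estimated correlation). Of 28 senescence-associated secretory genes, 12 rose and 5 fell with DMSO and 13 rose and 6 fell with WM-2474, with the growth factor binding proteins Igfbp7 up (0.74 and 0.93) and Igfbp5 down (-0.42 and -0.36). That list had an adjusted p = 0.045 and 0.0294, and an adjusted p = 0.165 and 0.121 with an estimated correlation.

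**Figure D4:**
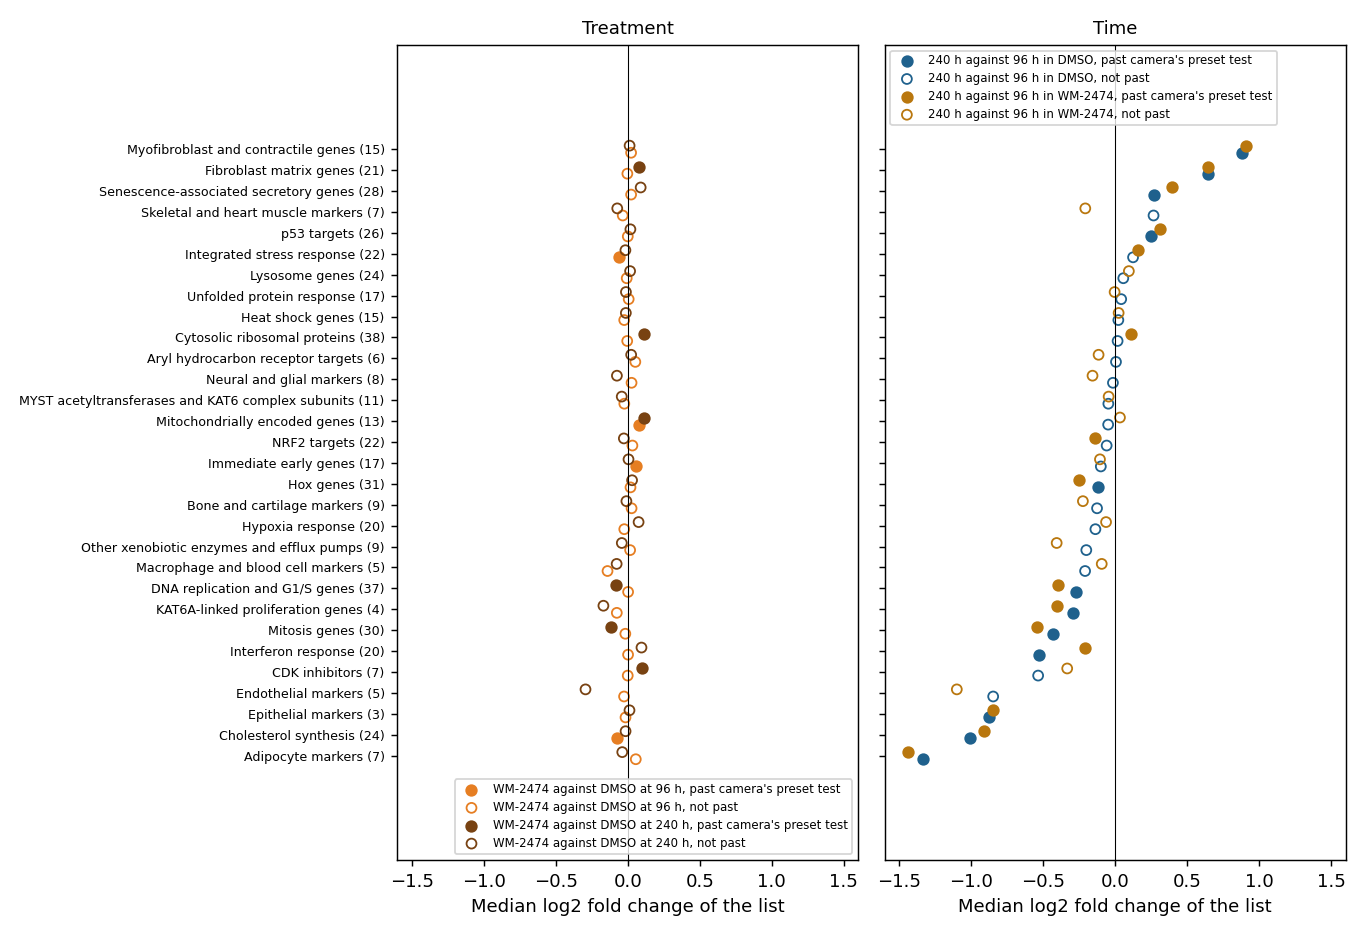
Median log2 fold change (x axis) of each gene list (y axis, number of tested genes in parentheses) for WM-2474 against DMSO on the left and 240 h against 96 h on the right, with filled points for lists called by camera with a preset correlation. Treatment medians lie between -0.29 (endothelial markers at 240 h) and 0.11, whereas cholesterol synthesis (-1.0 and -0.91), adipocyte (-1.34 and -1.44) and contractile genes (0.88 and 0.91) lie far from 0 in both time comparisons.

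Camera with a preset correlation called Hox, interferon response and epithelial genes lower over time, and none of these calls held with an estimated correlation. Among all 13499 tested genes, 2330 fell with DMSO and 1999 with WM-2474. The 3 of 20 interferon response genes that fell are near that share. Of 31 Hox genes, which give cells positional identity, 9 fell in each treatment, while 2 rose with DMSO and 3 with WM-2474. Hoxa5 fell by 1.39 ± 0.10 with DMSO and by 1.24 with WM-2474, and Hoxa7 by 1.05 in each, whereas Hoxd8 rose by 0.40 and 0.43 (list adjusted p = 0.0174 and 0.0126; adjusted p = 0.366 and 0.3 with an estimated correlation). Of 20 interferon response genes 3 fell in each treatment, with the transducer Stat2 at -0.86 ± 0.08 and -0.73 ± 0.08 and the GTPase Gbp2 at -1.23 ± 0.19 and -1.51 ± 0.21 (list adjusted p = 0.0323 and 0.0364; adjusted p = 0.474 and 0.442 with an estimated correlation). Of the 3 epithelial markers tested, 3 fell with DMSO and 2 with WM-2474, with keratin Krt19 at -0.88 and -0.85 (list adjusted p = 0.0359 and 0.0445, and 0.291 and 0.3 as adjusted p with an estimated correlation). In WM-2474 cultures camera also called NRF2 targets lower (2 rose and 8 fell of 22, adjusted p = 0.038) and the integrated stress response (10 rose and 1 fell of 22, adjusted p = 0.0294) and ribosomal proteins (10 rose and 1 fell of 38, adjusted p = 0.00295) higher, with an adjusted p = 0.291, 0.32 and 0.32 with an estimated correlation. The ribosomal median of 0.11 turned to -0.02 with library totals. Whether these lists differed between treatments was tested in the interaction above, where ribosomal and NRF2 genes were called with a preset correlation and not with an estimated one (adjusted p = 0.744 for both), and the integrated stress response (adjusted p = 0.16) was not called.

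Single genes with the largest changes over time were named by rule. Col15a1, which encodes a basement membrane collagen, rose from 11.4 ± 1.56 to 66.2 ± 3.46 CPM with DMSO (2.55 ± 0.09, adjusted p = 3.71e-17) and by 2.62 ± 0.10 with WM-2474. Heyl and Hey2, transcriptional repressors that act in the Notch pathway, rose by 4.01 ± 0.55 and 2.37 ± 0.33 with DMSO, and Heyl by 4.32 ± 0.66 with WM-2474. The peptide receptor subunit Ramp1 (2.44), the scaffold gene Ccdc88c (2.39), the guidance molecule Sema5b (2.32) and the epithelial envelope gene Sprr2k (2.45) were among the 10 largest rises with DMSO. The enzymes Galnt16 (2.56) and Cyp4b1 (2.64), the natriuretic peptide Nppb (2.34) and Fndc1 (2.31) were among those with WM-2474. Arhgap36 fell from 30.6 ± 9.17 to 2.73 ± 0.802 CPM with DMSO (-3.30 ± 0.36) and had a log2 fold change of -3.31 with WM-2474. Mesothelin, encoded by Msln, fell from 18.6 ± 4.37 to 2.14 ± 0.393 CPM with DMSO, and the leptin receptor Lepr fell by 3.05 ± 0.39. The kininogen Kng2 fell by 3.60 with DMSO and 3.68 with WM-2474, and the aminopeptidase Enpep by 3.17 with WM-2474. The acute phase gene Hp fell from 3.68 ± 0.722 to 0.106 ± 0.057 CPM with DMSO, and no fold is given since its 240 h level was at or under 3 counts per library.

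In all, 2364 genes were higher and 2330 lower at 240 h with DMSO (34.8% of those tested), of which 237 and 351 changed by over 2-fold. With WM-2474, 2147 were higher and 1999 lower (30.7%), 242 and 280 of them by over 2-fold. Libraries of both times did not overlap for 45.7% and 42.4% of genes, where chance gives 10%. Both comparisons called 1680 genes higher and 1538 lower, against 376 and 345 by chance, and 0 genes in opposite directions. The fold changes over time had a Pearson correlation of 0.849 and a Spearman correlation of 0.771 across genes. Replacing TMM factors with library totals moved the median change of all genes to -0.13 log2 with DMSO and -0.14 with WM-2474, and the changes reported here are relative to that shift. With library totals alone, 1190 genes were higher and 4381 lower with DMSO, 1097 and 4391 with WM-2474, and 4 and 5 lists were called lower in place of 8 and 9. Tested against a fold of 1.2, 719 were higher and 821 lower with DMSO and 700 and 732 with WM-2474, and without DMSO 240 h replicates 1 and 2 the DMSO counts were 1489 and 1374. Without DMSO 96 h replicate 1, 5 lists were lower with DMSO. The labels give no batch.

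**Figure D5:**
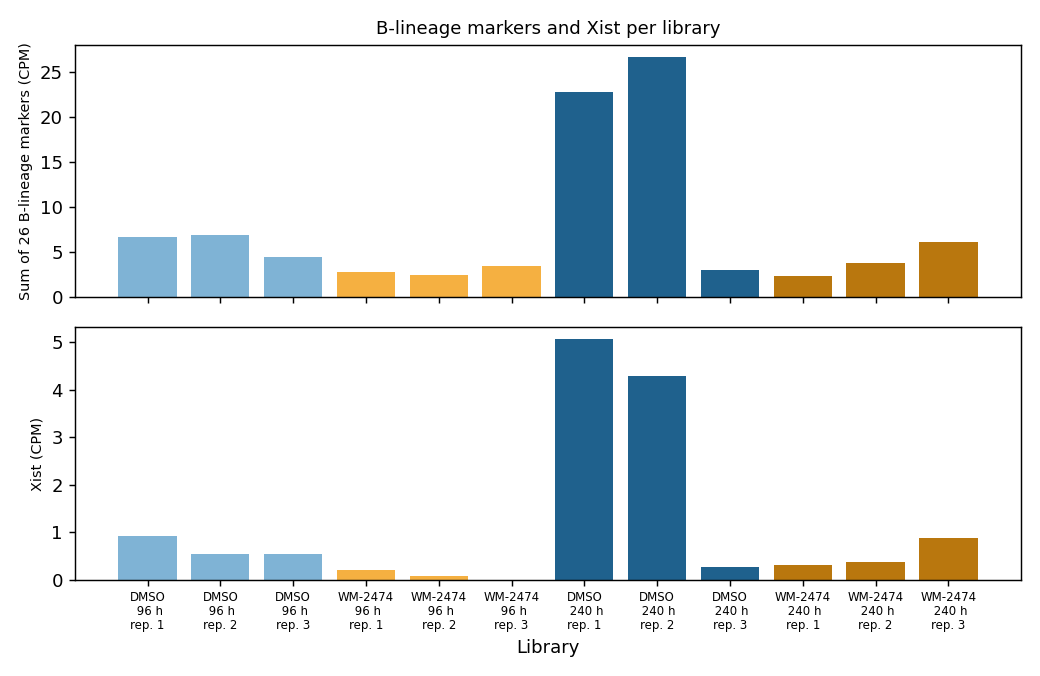
Summed CPM of 26 B-lineage markers (top) and CPM of Xist (bottom), both from 0 on the y axis, with a bar per library on the x axis coloured by group. DMSO 240 h replicates 1 and 2 stand at 22.8 and 26.7 CPM for the markers and 5.06 and 4.29 CPM for Xist, above the other 10 libraries.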

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

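The tests of gene length on the 4 genes, of copies of these genes, of counting noise in the B-lineage markers, and of other blood lineages over markers under 1 CPM elsewhere were chosen only after the results they measure were seen.

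Transcripts of B-lineage cells and Xist were found in DMSO 240 h replicates 1 and 2, the libraries with the fewest counts, with Ighm at 41 and 57 counts and Dntt at 20 and 38, while at 96 h these markers and Xist stood lower with WM-2474 (2.44 to 3.39 CPM in sum) than with DMSO (4.49 to 6.84), which chance gives in 10% of groupings, and 13 of 26 B-lineage markers lay above every other library in both (0.394 expected by chance). This expectation, like that for pan-leukocyte markers below, takes the pair of libraries as fixed beforehand. The pair was singled out by the 8 genes seen first, and markers of a shared source can move together. Blood cells of several lineages are argued against at a level that doubles the T-lineage, myeloid or red cell markers, since those under 1 CPM elsewhere reached 0.830 of the highest other library together and 0.803, 0.280 and 0.488 by list (upper 95% counting limits 1.24, 0.716 and 1.25), while smaller shares stay open and 6 of 9 red cell markers had 0 counts in all libraries. Counting noise at low depth is argued against as well, since the rate of the other libraries gives 29.8 and 31.4 counts where 167 and 206 were found (larger exact Poisson p = 1.62e-67). Reads or RNA of B-lineage cells from another sample may be the source and cannot be told apart from other sources. The marker sum was 3.34 times the highest other library, between the bounds of 2 and 4 set beforehand. The size of this ratio could not decide the question, since B-lineage cells in a culture could give it too. Xist stood at 5.06 and 4.29 CPM in the same libraries and at most at 0.929 CPM elsewhere. B-lineage cells of the male embryos alone would leave Xist unexplained, while female cells or RNA stay open as its source. No biological explanation was tested, since the design names no such cells; 8 of 13 pan-leukocyte markers, which B-lineage cells can express too, also lay above every other library in both (0.197 expected by chance), and the ratio was 2.39 for the 11 under 1 CPM elsewhere and 7.52 for the 8 genes seen first.

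Ptma, Tmsb10, Sorcs2 and Gm8623 were higher with WM-2474 at 240 h, where DMSO had the pair of libraries with the fewest counts. Removing each library's trend with gene length kept 0.932 of their median log2 fold change with all 4 called, which argues against that trend as the whole cause. Thinning every 240 h library to 7313007 counts kept 1.01 of it (0.34 against 0.33). Random thinning keeps each gene's expected share of a library, so that this result cannot decide about the depth gap. No gene passed at that depth (adjusted p = 0.0603 for each), while the median SE of the 4 genes went from 0.058 to 0.063. Near-identical copies are argued against for Sorcs2, which had 0, but reads of copies and of the gene itself cannot be told apart for Ptma and Tmsb10, where the table held 2 of 10 and 0 of 3 copies that added at most 0.249% of counts, nor for Gm8623, whose sum with Rps16 kept 0.922 of its fold change without passing (adjusted p = 0.399). Rps16 gave 59.6% of the summed counts and itself had a log2 fold change of 0.50 (adjusted p = 0.542 in edgeR). The share kept therefore cannot tell which of the genes changed. An effect of the compound remains an open hypothesis, and without DMSO 240 h replicates 1 and 2 the share kept was 0.938 with 0 genes called and a median SE of 0.082, where 1 DMSO library stood for its group and was assumed to vary like the others.

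Genes of cholesterol synthesis, mitosis and the matrix changed together between 96 h and 240 h. Scaling to library totals kept each list's direction, with a smallest median of 0.51 in that direction. TMM factors and totals differed by a mean of 0.128 log2 between the times, less than any of these medians. This argues against the choice between these scalings as the cause, and other errors of normalization were not tested. Removing the trend with gene length kept at least 0.972 of each median, which argues against that bias. The labels name no batch and none was tested. Culture time is the biological explanation that the design names, and it remains as a hypothesis.

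By the interaction test of camera, 5 lists had effects of WM-2474 that differed between the times. The median difference was 0.12 for cytosolic ribosomal proteins and 0.085 for the hypoxia response. It was -0.11 for DNA replication and G1/S genes, -0.11 for mitosis genes and -0.055 for NRF2 targets. With an estimated correlation their adjusted p lay between 0.744 and 0.788, so that none was called.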

How the results depend on the processing

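The fits of only the libraries compared with a replicate block or with limma-voom, and those without both DMSO 240 h libraries of fewest counts, were chosen after the data were seen. RLE size factors and the filter of over 1 CPM kept every count of called genes within 1.5 times of its main value. For single named genes, 3505 values of called results stayed past the threshold and 266 did not, 23 values of results not called passed, and 0 reversed. With library totals only, 0 genes were higher in the average; over time 1190 were higher and 4381 lower with DMSO and 1097 and 4391 with WM-2474, and 4 and 5 lists were lower. Without a filter (19626 genes) 39 genes were higher and 8 lower with WM-2474 at 240 h, 6 higher in the average and 2 in the difference. At 240 h DESeq2 called 11 genes higher, limma-voom 7, the replicate block 7, the fit of only the libraries compared 15, that fit with the replicate block 79 (and 12 lower), and limma-voom on those libraries 20. With the replicate block and only the 96 h libraries 3 genes were higher at 96 h, and with the block in all libraries 4 lists were higher in the difference. Correlations between libraries of the same replicate number all exceeded 0.1 at 96 h (0.301, 0.235 and 0.191). At 240 h they were weaker (0.0971, 0.114 and 0.0397) but above every pair of different numbers (at most 0.0231). Across times they were -0.00783 to 0.132, and with DMSO each lay above the pairs of different numbers (at most -0.0164). A weaker pairing outside 96 h therefore stays possible. Tested against a fold of 1.2, 0 genes passed at 240 h and 0 in the average, and over time 719 were higher and 821 lower with DMSO and 700 and 732 with WM-2474. Without both DMSO 240 h libraries of fewest counts, 0 genes were called at 240 h and 0 in the average, 1489 were higher and 1374 lower over time with DMSO, and 2 lists were higher at 240 h. With an estimated correlation 0 lists were called higher and 0 lower in each of the 6 contrasts. Fry called 0 lists higher and 0 lower in the 4 contrasts of treatment, and over time 8 higher and 12 lower with DMSO and 10 higher and 11 lower with WM-2474; it does not compare a list with other genes. Its mixed test, which ignores direction, called 3 lists at 240 h, namely ribosomal proteins and other enzymes and pumps for foreign compounds (adjusted p = 0.0222 each) and DNA replication (adjusted p = 0.0496), and 0 in the other 3 contrasts of treatment. At an unadjusted p under 0.01, 2 genes were higher at both times. Leaving out each library in turn gave 0 to 0 genes higher and 0 to 0 lower at 96 h and in the difference, 0 to 7 higher and 0 to 12 lower at 240 h, and 0 to 4 higher and 0 to 10 lower in the average. Over time it gave 1868 to 2328 higher and 1733 to 2265 lower with DMSO, and 1750 to 2162 and 1482 to 1881 with WM-2474. In the contrasts of treatment, genes were lower only where DMSO 240 h replicate 3 was left out. Lists called higher and lower ranged over 0 to 2 and 1 to 3 at 96 h, 2 to 4 and 2 to 2 at 240 h, 2 to 4 and 0 to 5 in the average, 1 to 5 and 0 to 3 in the difference, 3 to 4 and 5 to 9 over time with DMSO, and 5 to 6 and 7 to 9 with WM-2474. The log2 fold change at 240 h stayed within 0.29 to 0.35 for Ptma (past the threshold in 12 of 18 alternatives), 0.28 to 0.38 for Tmsb10 (11 of 18), 0.27 to 0.33 for Sorcs2 (12 of 18) and 0.53 to 0.60 for Gm8623 (11 of 18); in the average it was 0.21 to 0.27 for Ptma and 0.22 to 0.28 for Tmsb10 (11 of 21 each). Fewer libraries or genes tested and a stricter null account for some of these changes by construction; otherwise the cause was not tested. Depth limited DMSO 240 h replicates 1 and 2 most, where 3 counts corresponded to 0.410 and 0.390 CPM.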

Other observations

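The gene lists and the splits of the libraries in this part were fixed beforehand, except that the test on splits that part the 96 h pairs in the average was chosen only after the result was seen. Muscle, bone and nerve genes changed in a few members over time without a list call. For reference, 34.8% of all tested genes were called over time with DMSO and 30.7% with WM-2474. The cardiac troponin gene Tnnt2 rose by 1.68 ± 0.21 with DMSO and 1.51 ± 0.22 with WM-2474, and among 7 muscle markers 3 rose and 1 fell in each treatment, the falling member being cardiac actin Actc1 (-1.41 and -1.85). Of 9 bone and cartilage markers, the hypertrophic cartilage collagen Col10a1 rose (2.29 ± 0.53 and 2.16 ± 0.51) and 2 fell in each treatment, with the cartilage matrix protein gene Comp at -1.28 and -1.35. Of 8 neural markers, 2 rose and 1 fell with DMSO and 1 rose with WM-2474, with the microtubule protein gene Map2 at 1.75 ± 0.19 and 1.86 ± 0.20. Of 5 endothelial markers 1 fell with DMSO and 3 with WM-2474, with the growth factor receptor Kdr at -0.87 ± 0.28 and -1.26 ± 0.31. Of 5 macrophage and blood cell markers, 1 rose and 2 fell in each treatment, with Cd53 up (1.4 and 1.01), highest in DMSO 240 h replicates 1 and 2 (2.60 and 2.86 CPM, at most 2.27 elsewhere), and the lysozyme gene Lyz2 down (-2.71 with an interval of -3.53 to -1.88, and -1.18), to 3 and 2 counts in these libraries, at or under the floor.

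Stress and organelle genes were mixed over time and none of the following lists was called. Their counts stand beside 2364 genes that rose and 2330 that fell with DMSO among all 13499 tested. With WM-2474 2147 rose and 1999 fell. Of 20 hypoxia response genes 3 rose and 10 fell with DMSO and 3 rose and 7 fell with WM-2474, with the peptide hormone gene Adm at -1.48 ± 0.08 and -1.45 ± 0.08 and the collagen prolyl hydroxylase P4ha1 at 0.50 and 0.51. Of 15 heat shock genes 4 rose and 2 fell with DMSO and 5 rose and 2 fell with WM-2474, with the chaperone Hspa1b at 0.60 ± 0.05 and 0.79 ± 0.05 and Hsph1 at -0.22 and -0.19. Of 24 lysosome genes 7 and 9 rose and 4 fell in each, with the hexosaminidase Hexa at 0.46 and 0.50 and the galactosidase Gla at -0.52 and -0.67. Of 17 genes of the unfolded protein response 2 rose and 3 fell with DMSO and 3 rose and 4 fell with WM-2474, with Sel1l, a part of the machinery that degrades misfolded proteins, at 0.22 and 0.24. Of 17 immediate early genes 3 rose and 4 fell in each, with the phosphatase Dusp1 at 0.42 and 0.40 and the cytokine suppressor Socs3 at -1.05 and -0.70. Of 9 other enzymes and pumps for foreign compounds, 3 rose and 3 fell with DMSO and 2 rose and 4 fell with WM-2474, with the reductase Por at 0.27 and 0.23. Cyp1b1 fell among 6 aryl hydrocarbon receptor targets (-0.23 and -0.32), ND2 among 13 mitochondrially encoded genes (-0.20 and -0.17) and the acetyltransferase Kat5 (-0.28 and -0.29) among 11 acetyltransferase genes, where Kat7 also fell with WM-2474 (-0.17). The Y-linked Ddx3y (0.21 and 0.23) and Uty (0.22 and 0.27) rose among 5 sex-linked genes. In DMSO 22 NRF2 targets were not called (adjusted p = 0.460), with Ephx1 up (0.50) and Pgd down (-0.45). With library totals the medians of the heat shock and lysosome lists turned negative in both treatments, and those of the unfolded protein response and aryl hydrocarbon receptor lists, and of ribosomal proteins, did so with DMSO. That of mitochondrially encoded genes did so with WM-2474.

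Other splits of the same libraries were counted as a test of chance. Where the real count was 0 every split reaches it by construction, so that 10 of 10 splits at 96 h and 100 of 100 in the difference say nothing about chance. The highest other split gave 18 genes at 96 h, which points to a structure of the samples. That split parted 1 pair of equal replicate numbers, and among the 3 other splits that part all 3 pairs the highest count was 0. At 240 h 1 of 10 splits reached the real count of 4 genes and the highest other gave 3, and over time 1 of 10 reached the real count in each treatment, with a highest other of 0. With 10 splits no share under 0.05 is possible. In the average 6 of 100 splits gave at least the real count of 2 genes, with a highest other of 36. The drawn splits ignore the pairing at 96 h, and among the 80 splits that part all 3 pairs there, as the real one does, 4 gave at least 2 genes (a share of 0.05, highest other 3), so that chance is not excluded. In the difference the real count was 0 and the highest other 157. These splits with 36 and 157 genes point to a structure of the samples. Both kept the treatments apart at 240 h as in the real split and grouped WM-2474 96 h replicates 1 and 3 with a DMSO 96 h library, which parted 1 of the 3 pairs.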
